A study of Mus musculus with 20 samples.

How the data were processed

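The study measured gene expression by RNA sequencing in eosinophils sorted from mouse lung. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with the NEBNext Ultra II kit under an ultra-low input service, and each sample pooled lungs from 3 to 5 mice. Per the submitters' processing notes, the tools were bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2, with the mouse build mm10. The role and settings of each are not given in the sources used here. The authors deposited unnormalized counts per gene, whole numbers whose sums differ between libraries. The strand setting, the annotation release and the treatment of reads with several matches are not given in the sources used here, so values of near-identical paralogs (the globin genes, Bcl2a1 copies, Ear genes, guanylate-binding proteins and H2 genes) and of genes that overlap on opposite strands are uncertain. Donor and recipient belong to different strains, and reads from Balb/c cells can match the C57BL/6 reference less well.

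Each column was tied to a sample only where its name matched that sample's labels. This gave 5 columns for resting lung in one deposited table and 5 for day 7 without costimulatory blockade in another. A further 10 columns, headed by bare numbers that match no label, were not used in any step. Of 5 planned comparisons 1 was therefore run, and the 4 that involve the groups with blockade were not analysed here. Both tables hold counts for the same 49315 gene identifiers, no row without a gene, and they were joined by identifier. Symbols and coordinates came from GENCODE M21, which gave a symbol for 49056 identifiers and none for 259. Gene coordinates are the annotated span of the gene on mm10, counted from 1, and not single exons.

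Total counts per library were 6666577 to 12883144 in resting lung and 15695074 to 26683784 at day 7. A floor of 3 counts corresponds to 0.233 to 0.450 CPM in the resting libraries and to 0.112 to 0.191 CPM in the day 7 libraries, and it covers counting error only. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom was 6.6 or more for every pair.

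Genes with too few counts were removed with edgeR's filterByExpr by group, which left 16500 genes and removed 32815. Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, TMM scaling and group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The planned fit over all groups reduces to the 2 groups with columns. Log2 fold changes are day 7 without blockade minus resting, and standard errors were taken as the size of the log2 fold change divided by the square root of F. CPM values of single genes use TMM-scaled totals. The 39 gene lists (14 of cell type markers, 21 of functions and 4 of RNA quality, with 5 of 728 entries matching no identifier) were fixed before the data were examined and tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the 39 lists. Several lists share members: 11 of 22 surface genes, 12 of 22 type 2 genes, 9 of 15 eosinophil markers, 7 of 15 neutrophil markers 8 of 23 candidate genes for restraint of T cells, 7 of 25 interferon-gamma targets, 7 of 21 chemokines, 5 of 12 granule protein genes and 5 of 14 monocyte markers also stand in another list. None of the 29 lists called by camera kept its call with a correlation estimated per list.

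Single values per library were compared by exact two-sided permutation tests of the difference of means in scipy 1.17.1 (5 against 5, smallest p 0.00794), adjusted over 24 values. For these, CPM used library totals alone. The named genes follow a rule fixed before the data were examined: the 8 largest rises and 8 largest falls among called genes with an official symbol, at least 20 CPM in the higher group and no overlap between groups, up to 4 members of each list that passed camera or had at least 3 called members, and 12 genes always named. It gave 149 genes, of which a selection is printed, and some genes that the rule names are not reported here. Mbp, Serpinb2, Ctsg, Ear6, Csf2rb, Csf2rb2, Cxcl12, Ccl11, Ccl17, Jchain, Kit, Mx2, Gbp2, Ngp, Ltf, Nr4a2, Dusp2, Alox15, Kcnq1ot1, Lyz2 and Cd74, and the further markers in the closing tests, were named after their values were seen.

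Before use, the test was run on simulated data for this comparison, 16500 genes drawn from the real means, dispersions and library sizes with 200 changed. It recovered 42% of the 2-fold rises and 70.2% of the tested 2-fold falls, and 100% of the 4-fold rises and 84.1% of the tested 4-fold falls, and called 6 of 15990 unchanged genes. The simulation changed 200 genes, whereas the real comparison called 3843 higher and 3859 lower. With more called genes the adjusted threshold is less strict, so the recovered shares do not describe the real comparison. Smaller changes can still be missed there.

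Alternatives planned before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, no filter, a filter at 5 CPM in 5 libraries, a block for the replicate number, leaving out each library for genes and lists, camera with an estimated correlation, fry and a difference of medians. Added after seeing the data were thinning of every library to 6666577 counts, removal of trends with GC content and length (16464 genes had a value), scaling to library totals alone, protein-coding genes only, and leaving out each library for the single values. Plots were drawn with matplotlib 3.10.9.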

Results

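Eosinophils are granulocytes that release toxic granule proteins, cytokines and lipid mediators, and they also enter rejecting and tolerated organ grafts. The libraries here were made from eosinophils sorted by flow cytometry from mouse lungs, with the lungs of 3 to 5 mice pooled for each library. Recipients were of the C57BL/6 strain and donor lungs came from the Balb/c strain, so the graft was mismatched for the major histocompatibility complex (MHC). The labels describe the eosinophils as belonging to the recipient. They list 20 samples in 4 groups of 5: resting lung of untreated mice, and grafts at day 7 with costimulatory blockade, at day 30 with blockade and at day 7 without blockade. Costimulatory blockade is a treatment that withholds from T cells the accessory signals they need for activation. Sample labels could be tied to count columns for the resting lungs (n = 5) and for the day 7 grafts without blockade (n = 5). The 4 comparisons that need the groups with blockade were not analysed here. Total counts ranged from 6666577 to 12883144 per resting library and from 15695074 to 26683784 per day 7 library, a difference between group means with an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 can give.

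The comparison asks how libraries of eosinophils sorted from an allograft left without costimulatory blockade for 7 days differed from those of undisturbed lung. Interferon-induced genes and genes of antigen presentation by MHC class I were higher in the graft in nearly every case: 25 of 25 interferon-gamma targets, 29 of 30 interferon response genes and 20 of 20 class I genes. Cxcl9, a chemokine that draws activated T cells, went from 2.54 ± 1.18 CPM (counts scaled to the size of the library) in resting lung to 350.4 ± 138 CPM in the graft (mean ± SD, n = 5 each). Cd274, which encodes the inhibitory ligand PD-L1, went from 151 ± 33.7 to 1390 ± 662 CPM, and Nos2, the inducible nitric oxide synthase, from 4.65 ± 1.20 to 210 ± 134 CPM. Markers of monocytes and interstitial macrophages (12 of 14, median log2 fold change 2.04) and of T cells (12 of 12, median 2.30) were higher in the same libraries. Genes of lung endothelium, epithelium, red cells and platelets went the other way, with Kdr, an endothelial growth factor receptor, falling from 352 ± 54.99 to 15.6 ± 4.09 CPM. The genes of the eosinophil surface receptors Ccr3 and Il5ra did not pass the test, while the granule protein genes Prg2 and Epx fell.

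Of 16500 genes tested with edgeR's quasi-likelihood test, 3843 were higher and 3859 lower in the day 7 grafts at an adjusted p below 0.05, and 1498 and 2683 of these differed by at least 2-fold in the same directions. The share of higher genes among those called was 49.9%. Scaling to library totals alone, without correction for composition, lowered the median log2 fold change of all genes by 0.19 and gave 2495 higher and 4883 lower, or 33.8% higher. The libraries of the 2 groups did not overlap in 35.1% of genes, against 0.79% from chance. The resting and the day 7 columns stood in separate tables and differed in depth, so a difference between batches cannot be told apart from the difference between groups. Each library is a pool from several mice, and nothing in the labels says that the mice of different pools were housed or operated on independently, so p-values measure the spread between pools.

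**Figure D1:**
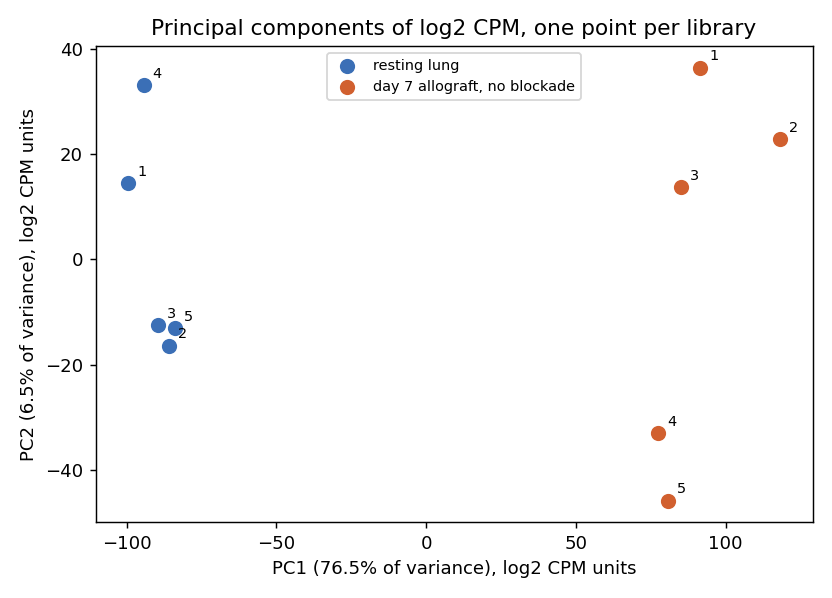
Each point is 1 library placed by the first and the following principal component of log2 CPM over the genes tested, with the replicate number beside it and the group in colour. The axis that holds 76.5% of the variance separates the 5 resting from the 5 day 7 libraries, and the vertical axis holds 6.5%.

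Among genes with an official symbol, at least 20 CPM in the higher group and no overlap between the groups, the largest rises were those of Saa3, Cxcl9, Arg1, Gbp2b, Pdcd1, Cyp26a1, Ccl8 and Nos2. Saa3, an acute phase apolipoprotein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, mm10), rose by a log2 fold change of 7.23 ± 0.42 (SE, quasi-likelihood adjusted p = 2.86e-08). Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) rose by 7.10 ± 0.42 (adjusted p = 3.62e-08). Arg1, the arginase that consumes L-arginine (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), went from 2.28 ± 1.07 to 278 ± 175 CPM. Pdcd1, which encodes the inhibitory receptor PD-1 of activated T cells, went from 1.67 ± 0.55 to 105 ± 33.5 CPM. The largest falls were those of Bpifa1, Cyp1a1, Tmem100, Kif26a, Npr3, Bpifb1, Wscd1 and Inmt. Bpifa1, a secreted protein of the airway epithelium (ENSMUSG00000027483, chromosome 2, 154142880 to 154149219), fell by 9.31 ± 0.97 on the log2 scale, but resting replicate 1 had 1492 CPM of it and without that library the log2 fold change was -8.0. Without day 7 replicate 1 it was -9.92. Tmem100, a membrane protein of lung endothelium (ENSMUSG00000069763, chromosome 11, 90030348 to 90036508), had 181 ± 34.0 CPM in resting lung and 0.62 ± 0.24 CPM in the graft. Cyp1a1 and Npr3 had 5 and 19 counts in all in the day 7 libraries, and their log2 fold changes of -8.38 and -7.98 became -9.85 and -8.74 without day 7 replicates 2 and 1.

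The list of guanylate-binding proteins, immunity-related GTPases and other interferon-gamma targets had a median log2 fold change of 3.21 (camera adjusted p = 1.66e-13, adjusted p = 0.217 with an estimated correlation). Within it Cxcl10 rose from 87.0 ± 10.2 to 1569 ± 366 CPM, Socs1, a feedback inhibitor of cytokine signalling, from 9.49 ± 2.33 to 134 ± 26.2 CPM and Serpina3g from 26.2 ± 9.28 to 483 ± 145 CPM. The broader interferon response list had a median of 1.91 (camera adjusted p = 1.66e-13, adjusted p = 0.262 with an estimated correlation). Irf8, a transcription factor induced by interferon, rose by 2.45 ± 0.18 on the log2 scale. Zbp1, a nucleic acid sensor, rose from 41.3 ± 12.4 to 425 ± 82.3 CPM, and Mx2 was the member that did not pass, with 4.54 CPM in resting lung and 6.81 CPM in the graft. Adjusted over the list alone, 25 and 29 members were higher in these lists, as over all genes. The MHC class I list had a median of 1.58 (camera adjusted p = 5.31e-13, adjusted p = 0.172 with an estimated correlation), and all 20 members were also higher when adjusted over the list alone. Tap1, a subunit of the peptide transporter that loads class I molecules (ENSMUSG00000037321, chromosome 17, 34187553 to 34197225), went from 151 ± 24.2 to 982 ± 193 CPM. Nlrc5, the transactivator of class I genes, rose by 2.88 ± 0.16, the immunoproteasome subunit gene Psmb9 by 2.47 ± 0.16 and the proteasome activator gene Psme2 by 2.18 ± 0.14 on the log2 scale. Class I genes and the paired GTPase genes share sequence with their neighbours, and how the authors counted reads with several matches is not given in the sources used here, so the split between paralogs such as Gbp2 and Gbp2b is uncertain. In the same libraries the summed CPM of monocyte and interstitial macrophage markers rose from 8806 ± 2203 to 17176 ± 4227 and that of T cell markers from 148 ± 27.3 to 642 ± 231 (adjusted exact permutation p = 0.0224 and 0.0159).

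Genes of MHC class II presentation and costimulation were higher in 12 of 17 cases and lower in 1. Their median log2 fold change was 1.97 (camera adjusted p = 0.000119, adjusted p = 0.269 with an estimated correlation). There were 13 higher and 1 lower when adjusted over the list alone. H2-Eb1, a class II beta chain, rose from 287 ± 63.2 to 1700 ± 885 CPM, Cd86, a ligand of the T cell receptors CD28 and CTLA-4, from 45.3 ± 6.98 to 242 ± 96.8 CPM and Cd40 from 20.6 ± 3.74 to 131 ± 57.6 CPM. Cd80, the other ligand of CD28 measured, did not pass, with 127 ± 30.2 and 185 ± 63.4 CPM. The list of candidate genes for restraint of T cells had 17 of 23 members higher and 1 lower, over all genes and adjusted over the list alone. Their median was 1.5 (camera adjusted p = 2.31e-05, adjusted p = 0.172 with an estimated correlation). Its higher members included Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), with a log2 fold change of 3.21 ± 0.29 (adjusted p = 1.31e-06), Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), with 5.48 ± 0.47 (adjusted p = 8.91e-07), Arg1, and Il1rn, the interleukin-1 receptor antagonist, with 2.06 ± 0.21. Tgfb1 did not pass, at 192 ± 18.05 CPM in resting lung and 212 ± 18.1 CPM in the graft. Class II genes, Cd86 and Cd40 are also made by macrophages and dendritic cells, and Nos2, Arg1 and Cd274 by activated macrophages. Markers of monocytes and interstitial macrophages were higher in 12 of 14 cases and those of dendritic cells in 6 of 11, with medians of 2.04 and 0.64. Of the dendritic cell markers 1 was lower, Zbtb46, from 38.1 ± 8.18 to 15.1 ± 3.17 CPM. Dendritic cell markers summed to 1111 ± 170 CPM in resting lung and 1226 ± 117.5 CPM in the graft (exact two-sided permutation p = 0.294).

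**Figure D2:**
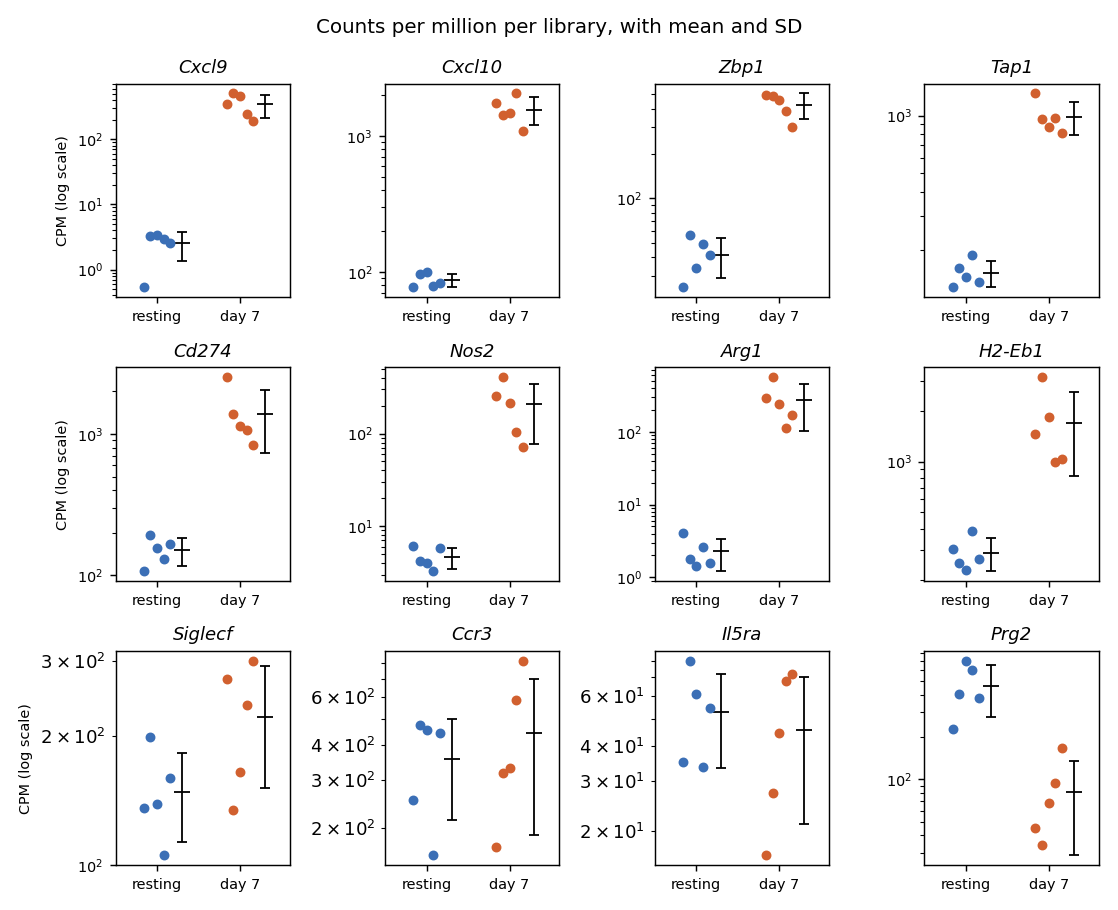
CPM of 12 genes in each library on log axes, with resting lung in blue, day 7 grafts without blockade in orange, and the mean and SD of 5 libraries as a black bar. The groups do not overlap for Cxcl9, Cxcl10, Zbp1, Tap1, Cd274, Nos2, Arg1, H2-Eb1 and Prg2, and they overlap for Siglecf, Ccr3 and Il5ra.

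Chemokine genes were higher in 16 of 21 cases and lower in 3, over all genes and adjusted over the list alone. Their median log2 fold change was 1.87 (camera adjusted p = 3.90e-05, adjusted p = 0.172 with an estimated correlation). Ccl8 and Ccl12, ligands for monocyte receptors, rose from 1.28 ± 0.61 to 72.4 ± 21.7 CPM and from 1.62 ± 0.79 to 44.6 ± 14.7 CPM. Cxcl12, Ccl11 and Ccl17 fell, by 4.02, 2.56 and 1.80 on the log2 scale, beside lower endothelial markers (10 of 10, median -5.10). Among receptors for chemokines and lipid attractants 14 of 24 were higher and 2 lower. Their median was 0.65 (camera adjusted p = 0.00213, adjusted p = 0.172 with an estimated correlation). This became 14 higher and 3 lower when adjusted over the list alone. C3ar1, the receptor of the complement fragment C3a, rose from 78.3 ± 21.9 to 336 ± 76.8 CPM. S1pr1, a sphingosine 1-phosphate receptor that is abundant in endothelium, fell from 362 ± 43.1 to 49.9 ± 10.2 CPM. NF-kB and TNF target genes were higher in 20 of 27 cases and lower in 0, over all genes and adjusted over the list alone. Their median was 1.08 (camera adjusted p = 2.63e-05, adjusted p = 0.283 with an estimated correlation). Sod2, the mitochondrial superoxide dismutase, rose by 2.29 ± 0.26 on the log2 scale and Nfkbie, an inhibitor of NF-kB, by 0.82 ± 0.14. Monocyte and macrophage markers, whose cells express many genes of these lists, rose alongside.

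Of 15 eosinophil markers measured, 4 were higher, 4 lower and 7 did not pass, over all genes and adjusted over the list alone, and the list gave no call (camera adjusted p = 0.926). Its median log2 fold change was 0.11, its mean -0.39, and its median with library totals alone -0.06. The 4 lower members all encode granule proteins. Epx, the eosinophil peroxidase (ENSMUSG00000052234, chromosome 11, 87864000 to 87875536), fell from 93.1 ± 69.1 to 6.89 ± 3.83 CPM (adjusted p = 0.000446). Prg2, which encodes major basic protein (ENSMUSG00000027073, chromosome 2, 84980461 to 84983632), fell from 463 ± 186 to 81.5 ± 52.7 CPM (adjusted p = 0.000303), and Prg3 and Ear6 fell by 2.81 ± 0.40 and 1.79 ± 0.45 on the log2 scale. The call of Ear6 ended without a filter on low counts (adjusted p = 0.0554). Ccr3, the eotaxin receptor (ENSMUSG00000035448, chromosome 9, 124021972 to 124031689), had 356 ± 141 CPM in resting lung and 443 ± 254 CPM in the graft (adjusted p = 0.548), and Il5ra had 52.9 ± 19.3 and 45.7 ± 24.5 CPM (adjusted p = 0.673). Siglecf, the sialic acid-binding receptor used to sort mouse eosinophils (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531), rose from 148 ± 34.5 to 222 ± 70.2 CPM with an adjusted p of 0.0465. This call ended under 7 of the other settings (adjusted p up to 0.158), and also without resting replicate 1, 3, 4 or 5 or day 7 replicate 1, 4 or 5 (adjusted p up to 0.101). Il1rl1, the interleukin-33 receptor, rose from 28.9 ± 7.25 to 68.2 ± 28.0 CPM. Csf2rb, the beta chain shared by the receptors for interleukin-3, interleukin-5 and GM-CSF, and its close relative Csf2rb2 were higher as well, by 1.21 and 1.51 on the log2 scale.

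Across the granule protein list 9 of 11 members fell and 2 rose, over all genes and adjusted over the list alone. Their median was -2.04 (camera adjusted p = 0.0142, adjusted p = 0.421 with an estimated correlation). The 2 that rose were Gzmb, a granzyme of cytotoxic lymphocytes, from 44.2 ± 10.8 to 282 ± 92.7 CPM, and Serpinb2, an inhibitor of plasminogen activators, from 178 to 597 CPM. The 9 that fell include Mbp, which despite its symbol encodes the myelin basic protein, and Ctsg, a protease of neutrophil granules. In the same libraries the neutrophil granule genes Camp, Ngp and Ltf fell. Among surface genes reported to separate resident from inflammatory eosinophils 12 of 22 were higher and 0 lower, and 16 and 0 when adjusted over the list alone. Their median was 0.47 (camera adjusted p = 0.000208, adjusted p = 0.172 with an estimated correlation). With library totals alone 8 were higher and 1 lower. The test took no account of which state each gene marks, so its direction favours neither state. Fcgr3 and Fcgr2b, receptors for immunoglobulin G, rose by 2.00 ± 0.14 and 1.52 ± 0.20 on the log2 scale. Markers of monocytes and interstitial macrophages, which also carry these receptors, rose in the same libraries (12 of 14 higher, median 2.04). Cd101 had 47.4 ± 18.7 and 52.9 ± 26.3 CPM and did not pass (adjusted p = 0.726). Type 2 effector genes were higher in 6 of 20 cases and lower in 4, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.174). Retnla, a secreted product of alternatively activated macrophages, went from 37.1 ± 9.79 to 1477 ± 1640 CPM. Day 7 replicate 5 had 4345 CPM, and without it the log2 fold change of 5.31 became 4.36. Areg, an epidermal growth factor receptor ligand, rose from 4.98 ± 1.21 to 26.3 ± 11.2 CPM.

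**Figure D3:**
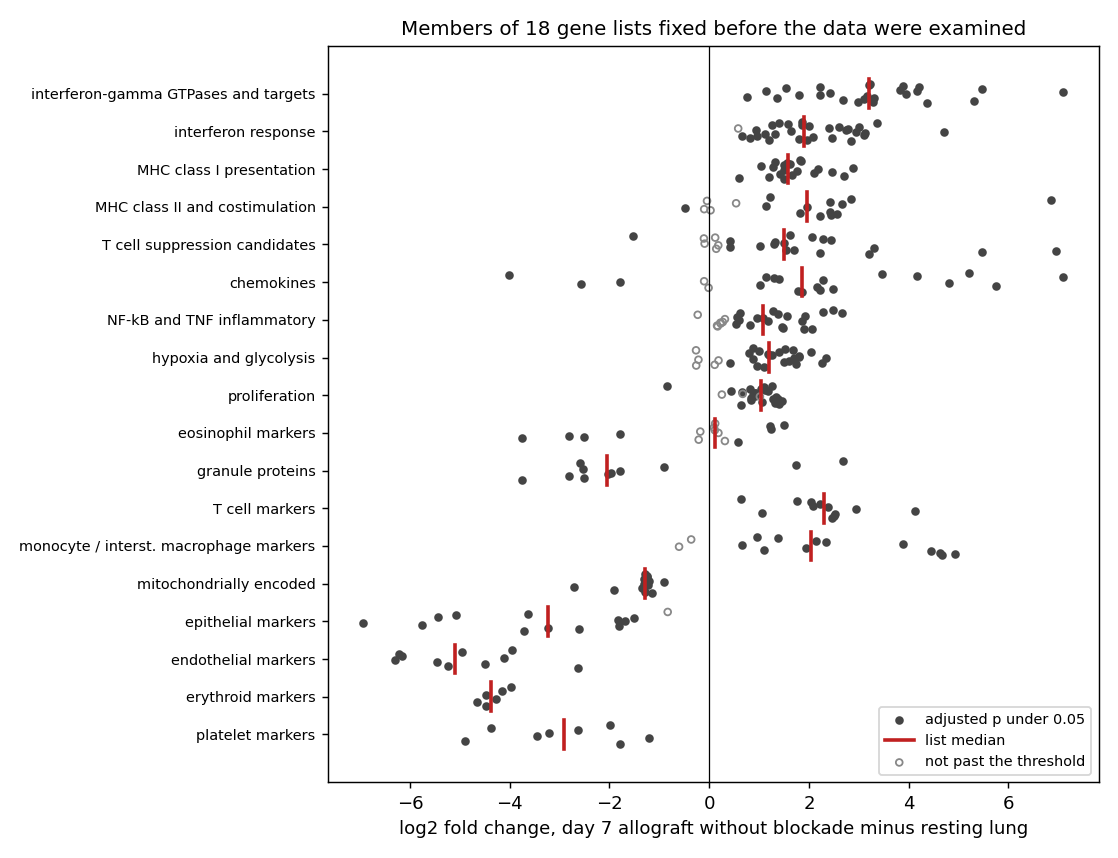
Log2 fold change of each measured member of 18 gene lists, with filled points for an adjusted p under 0.05, open points for the rest and a red bar at the list median. The medians of the interferon and MHC lists lie to the right of 0, all endothelial, erythroid and platelet markers lie to the left, and the point farthest right in the class II list is Tnfsf4, which had 2 counts in all in the resting libraries.

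Genes of glycolysis and the hypoxia response were higher in 22 of 27 cases and lower in 0, over all genes and adjusted over the list alone. Their median log2 fold change was 1.19 (camera adjusted p = 7.17e-07, adjusted p = 0.283 with an estimated correlation). Tpi1, Pgk1 and Gapdh, enzymes of glycolysis, rose by 2.34 ± 0.18, 1.81 ± 0.17 and 1.69 ± 0.16 on the log2 scale, and Gapdh went from 509 ± 35.9 to 1647 ± 394 CPM. Nuclear genes of oxidative phosphorylation were higher in 28 of 38 cases, and 30 when adjusted over the list alone, by a smaller median of 0.38 (camera adjusted p = 5.49e-06, adjusted p = 0.283 with an estimated correlation). With library totals alone 16 of these were higher and 1 lower. Both lists rose in libraries whose monocyte and interstitial macrophage markers also rose (12 of 14 higher, median 2.04). The 13 measured genes encoded by the mitochondrial genome all fell, over all genes and adjusted over the list alone. Their median was -1.28 (camera adjusted p = 3.22e-05, adjusted p = 0.338 with an estimated correlation), and their share of all counts went from 1.97 ± 0.42% to 0.80 ± 0.30% (exact two-sided permutation p = 0.00794). This list was one of RNA quality, and markers of endothelium, epithelium and red cells fell in the same libraries. The cells behind the fall were not tested, so it does not show a change of metabolism in eosinophils. Cell cycle genes were higher in 25 of 29 cases and lower in 1. Their median was 1.04 (camera adjusted p = 4.80e-07, adjusted p = 0.283 with an estimated correlation). The counts were 26 and 1 when adjusted over the list alone. Top2a, which untangles DNA in dividing cells, rose from 16.6 ± 2.43 to 44.0 ± 10.6 CPM and Mcm6, part of the replicative helicase, from 33.2 ± 5.56 to 71.9 ± 11.3 CPM. T cell markers rose in the same libraries.

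Markers of cell types other than eosinophils differed between the groups in both directions, although the cells had been sorted. All 10 endothelial markers fell. Their median log2 fold change was -5.10 (camera adjusted p = 5.05e-09, adjusted p = 0.172 with an estimated correlation). Cdh5, the junction protein VE-cadherin, went from 173 ± 26.5 to 4.59 ± 1.92 CPM. Epithelial markers were lower in 12 of 13 cases. Their median was -3.24 (camera adjusted p = 4.74e-06, adjusted p = 0.283 with an estimated correlation). Ager, a marker of alveolar type 1 cells, went from 282 ± 75.1 to 6.47 ± 2.94 CPM. All 6 erythroid markers measured fell. Their median was -4.37 (camera adjusted p = 2.43e-06, adjusted p = 0.217 with an estimated correlation). All 8 platelet markers fell. Their median was -2.92 (camera adjusted p = 1.38e-05, adjusted p = 0.172 with an estimated correlation). Mesenchymal markers were lower in 6 of 11 cases and higher in 2. Their median was -0.95 (camera adjusted p = 0.0196, adjusted p = 0.481 with an estimated correlation). Pdgfra fell from 79.4 ± 13.9 to 4.50 ± 2.29 CPM. With library totals alone the 2 higher mesenchymal genes lost their call, and without day 7 replicate 2 the list lost its own (adjusted p = 0.0568). Adjusted over the list alone, the counts for these 5 cell types were unchanged from those over all genes.

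Markers of leukocytes went in several directions. All 12 T cell markers rose, over all genes and adjusted over the list alone. Their median was 2.30 (camera adjusted p = 2.27e-07, adjusted p = 0.262 with an estimated correlation). Cd8a went from 4.50 ± 1.55 to 77.1 ± 40.2 CPM. Natural killer cell markers were higher in 7 of 10 cases, and in 9 when adjusted over the list alone. Their median was 1.30 (camera adjusted p = 0.000662, adjusted p = 0.283 with an estimated correlation). Monocyte and interstitial macrophage markers were higher in 12 of 14 cases. Their median was 2.04 (camera adjusted p = 3.62e-05, adjusted p = 0.283 with an estimated correlation). They were 12 higher and 1 lower when adjusted over the list alone. C1qa, C1qb and C1qc, the complement C1q chains made by macrophages, rose by 4.67 ± 0.41, 4.93 ± 0.42 and 4.62 ± 0.38 on the log2 scale. Alveolar macrophage markers were lower in 6 of 14 cases and higher in 3. Their median was -0.53 (camera adjusted p = 0.0318, adjusted p = 0.283 with an estimated correlation). The counts were 7 lower and 3 higher when adjusted over the list alone, and the list's call ended with library totals alone (adjusted p = 0.0632) and without day 7 replicate 5 (adjusted p = 0.054). Dendritic cell markers were higher in 6 of 11 cases and lower in 1, over all genes and adjusted over the list alone. Their median was 0.64 (camera adjusted p = 0.0443, adjusted p = 0.217 with an estimated correlation). The call ended at equal depth (adjusted p = 0.0536), with GC and length trends removed (adjusted p = 0.0542) and without day 7 replicate 2 (adjusted p = 0.0703). B and plasma cell markers were lower in 7 of 11 cases and higher in 1, over all genes and adjusted over the list alone. Their median was -0.86 (camera adjusted p = 0.0177, adjusted p = 0.437 with an estimated correlation). Ebf1, a B cell transcription factor, fell by 1.49 ± 0.16 on the log2 scale, and Jchain, the joining chain of secreted antibodies, was the member that rose. Neutrophil markers gave no call (camera adjusted p = 0.0969), with 3 of 15 lower over all genes and adjusted over the list alone: Camp, Ngp and Ltf, all made at early stages of granulocyte maturation. The list passed without resting replicate 5 (adjusted p = 0.0482) or day 7 replicate 1 (adjusted p = 0.0113). Mast cell and basophil markers gave none either (camera adjusted p = 0.926), with 2 of 8 higher and 1 lower over all genes and adjusted over the list alone. Their median was 0.45, but their summed CPM fell from 249.5 ± 38.9 to 148 ± 67.5 (exact two-sided permutation p = 0.0159, adjusted 0.0224), and Kit, the lower member, fell from 140 ± 19.5 to 28.8 ± 1.70 CPM. Kit made up much of that sum in resting lung, so the fall of the sum does not show fewer mast cells or basophils.

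Summed over each list and scaled to library totals, eosinophil markers took 4210 ± 927 CPM in resting lung and 4320 ± 1074 CPM in the graft (exact two-sided permutation p = 0.857). This sum joins 4 higher members, among them Csf2rb from 425 to 984 CPM, and 4 lower ones, among them Prg2 from 463 to 81.5 CPM. A level sum therefore does not show that the share of eosinophils was unchanged. Neutrophil markers took 11424 ± 1060 and 7715 ± 1987 CPM (exact p = 0.0159). Endothelial markers took 2594 ± 431 and 127 ± 30.0 CPM, epithelial markers 4557 ± 870 and 305 ± 175 CPM, erythroid markers 1738 ± 324 and 71.0 ± 20.4 CPM and platelet markers 346 ± 80.5 and 62.8 ± 9.56 CPM, each with an exact p of 0.00794 and an adjusted exact p of 0.0159 over 24 such values.

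**Figure D4:**
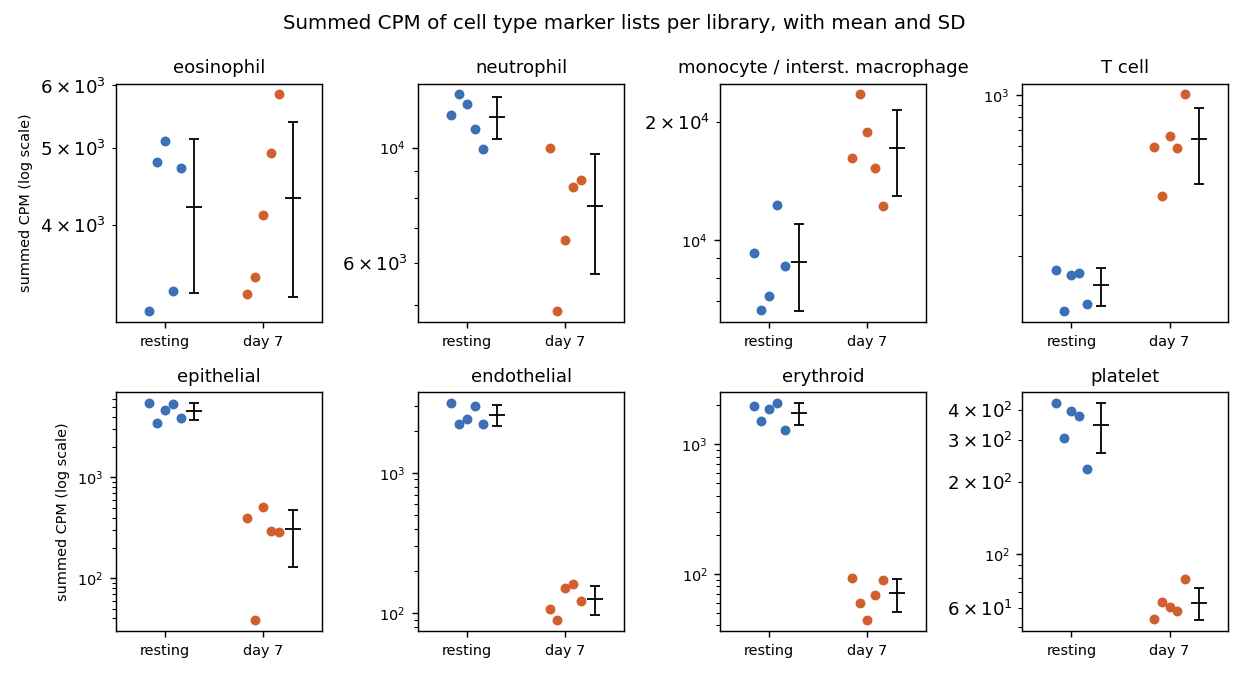
Summed CPM of the markers of 8 cell types in each library on log axes, with resting lung in blue, day 7 grafts without blockade in orange, and the mean and SD of 5 libraries as a black bar. Eosinophil sums overlap between the groups, endothelial sums lie between 2217 and 3132 CPM in resting lung and between 89.7 and 161 CPM in the graft, and T cell sums rise from at most 172 to at least 364 CPM.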

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

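Tests of the share of eosinophils, of RNA from other lung cells, of RNA from monocytes or T cells, of fewer eosinophils at day 7 and of immature granulocytes were chosen after the results they bear on, or some of their genes, had been seen. In 21 of 346 groups of 5 libraries 1 library stood far from the others by Dixon's criterion on log2 of CPM plus 0.5. Chance gives about 1 in 20 groups, or 17.3 here.

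Of the 21, 6 concern day 7 replicate 2. The summed CPM of epithelial markers was 38.5 (others 287 to 514). CPM was 0.55 for Epx (5.97 to 9.62), 1.37 for Cdh5 (4.53 to 6.33), 1.54 for Ager (7.00 to 9.45), 25.6 for Top2a (44.7 to 51.7) and 52.6 for Mcm6 (72.3 to 82.0). Day 7 replicate 4 was low for Ccl8 (36.2 against 70.6 to 92.3 CPM) and Areg (7.91 against 27.0 to 37.8 CPM), and day 7 replicate 1 was high for Nlrc5 (502 against 325 to 366 CPM) and Spp1 (735.5 against 420.5 to 485 CPM). In resting replicate 1, Bpifa1 had 1492 CPM (161 to 198 in the others), mt-Nd4l 22.4 CPM (10.9 to 12.4), Tagln 10.8 CPM (7.57 to 8.16) and Cxcl9 0.53 CPM (2.52 to 3.41). Resting replicate 2 had 92.2 CPM of Sod2 (106 to 111), 11.1 CPM of Cidec (15.6 to 17.1) and 0.20 CPM of Tnfsf4, whose 2 counts all lay there. Resting replicate 4 had 27.0 CPM of Cd40 (17.9 to 20.1) and 108 CPM of Irf8 (65.1 to 71.3), replicate 3 had 119 CPM of Pfkp (136 to 143) and replicate 5 had 26.1 CPM of Gzmb (44.0 to 54.1). Leaving out the library changed no call of the gene concerned, but the log2 fold change of Bpifa1 went from -9.31 to -8.0, and with 2 resting counts that of Tnfsf4 cannot be sized.

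A random labelling of the libraries is argued against as the source of the counts of genes. Every other split mixes the 2 groups, which widens the spread within each set if the groups differ for any reason. The splits therefore cannot show what a difference between batches would give. Of 100 splits of the 10 libraries into 5 and 5, 1, the real one, gave as many genes in a single direction as the 3843 that were higher, and 1 gave as many as the 3859 that were lower, and the highest of the other splits gave 186.

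The first pattern is the loss of structural, red cell and platelet transcripts from the day 7 libraries. A changed share of eosinophils that raises every other cell type alike is argued against by the medians of the monocyte and T cell lists, the lower of which lay 4.96 above the highest of the 4 structural medians. Depth is argued against as well, since 100% of the 36 called members were still lower at equal depth. RNA or cells of other lung types in the resting libraries remain open: 15 further markers of these types, 13 of them measured, had a median log2 fold change of -4.32, with 12 lower, including Calcrl from 713 to 20.7 CPM and Cav1 from 701 to 20.5 CPM. Gypc, the only further red cell marker measured, did not pass (14.2 to 17.4 CPM), so this set does not bear on red cells. The flow cytometry sort is meant to remove such cells, and free RNA, a difference between batches or a graft that holds fewer of them may each contribute, none of which the design separates.

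The next pattern is the rise of interferon and MHC class I genes. Depth is argued against, since 100% of the 74 called members of the 3 lists stayed higher at equal depth, and so is a bias with GC content or gene length, since 100% of the 74 stayed higher with those trends removed. RNA from monocytes, macrophages or T cells cannot be told apart from a response of the eosinophils, because the monocyte and macrophage list itself rose with a median log2 fold change of 2.04 and the genes are induced in most cell types. Lyz2 and Cd74, abundant in macrophages but not restricted to them, reached 11595 and 8457 CPM at day 7, from 6001.5 and 2160.0 CPM in resting lung. The sort is meant to remove macrophages, and these values do not show how many passed it.

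The last pattern is the fall of granule protein genes beside receptor genes that did not fall. Fewer eosinophils at day 7 would lower receptor genes along with granule genes. The median log2 fold change of 8 receptor genes was 0.45 with 0 lower, and that of Epx, Prg2, Prg3 and Ear6 was -2.66, a gap of 3.11. Ccr3 changed by 0.31 ± 0.39 and Il5ra by -0.21 ± 0.37. Several of the 8 may also come from monocytes and macrophages, whose markers rose (12 of 14, median 2.04), so the receptor median decides nothing. The changes of Ccr3 and Il5ra lay above the granule median by more than their SE. For Ccr3 and Il5ra the values argue against fewer eosinophils as the only cause of a fall that large. A smaller loss of eosinophils is not excluded. The pattern was defined by these genes after they had been seen, so the gap is no independent test of any cause. Immature granulocytes, or their RNA, in the resting libraries are a candidate source, since granule protein genes are transcribed mainly during maturation and 8 genes of immature granulocytes outside the granule and neutrophil lists had a median log2 fold change of -2.56, although the flow cytometry sort is meant to remove such cells. Of these 5 were lower, among them Elane from 98.4 to 5.11 CPM and Mpo from 183 to 12.3 CPM. Cebpe, Gfi1 and Chil3 did not pass, with log2 fold changes of 0.09, 1.10 and -0.52, so Gfi1 leaned the other way. The median of -3.03 with Ctsg, Camp, Ngp and Ltf included decides nothing, as these were already known to be lower. None of these values shows whether eosinophil precursors were among the immature granulocytes. A lower transcription of granule genes in mature graft eosinophils was not tested and stays open, as does a difference between batches.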

How the results depend on the processing

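Thinning, removal of GC and length trends, library totals alone and protein-coding genes only were chosen after seeing the data, as were leaving out libraries for the single values and the settings of 28 genes named later. Without a filter on low counts 42249 genes were tested, and 4862 were higher and 6715 lower, so the lower count exceeded the main 3859 by over 1.5 times. More low genes were tested, and the quasi-likelihood adjusted p of abundant genes moved too, that of Calcrl from 1.94e-09 to 7.78e-219. Which of these gave the added calls was not tested, and calls gained without a filter carry this limit. With library totals alone 2495 genes were higher against 3843, since the scaling moved the median of all genes by -0.19. It gave 4883 lower. The other settings gave 2952 to 4125 higher and 2711 to 4171 lower, and leaving out 1 library 3507 to 3976 higher and 3669 to 4020 lower. The call of 1 gene turned, that of Kcnq1ot1, from a log2 fold change of -0.49 to 0.52 with GC and length trends removed. Camera called 29 lists, 0 with an estimated correlation (smallest adjusted p 0.172, the cause was not tested), 34 by fry, which does not compare a list with other genes, 28 or 29 under the other settings and 27 to 31 without 1 library. Among the other genes named in the text, Siglecf lost its call in 7 settings (adjusted p up to 0.158) and Ear6 without a filter (adjusted p = 0.0554). Cd80 (adjusted p = 3.11e-05), Mx2 (0.0266), Gfi1 (0.0141) and Chil3 (0.0256) gained one without a filter. Gfi1, as higher, also gained one at equal depth (0.0445). Chil3, as lower, also gained one with trends removed (0.0312) and with library totals alone (0.0343). Without 1 library the calls of Siglecf, Cd80, Mx2 and Gfi1 changed in 7, 2, 1 and 1 fits, and the log2 fold changes of Elane and Jchain moved by -0.62 and 0.59. Among 24 single values 17 passed, 17 or 18 without 1 library, and 0 with medians, whose smallest exact p of 0.0476 does not survive adjustment. A replicate block gave 3317 higher and 3636 lower and 29 lists. Libraries with the same number did not deviate together (correlations -0.188 to 0.12), which gives no sign of a pairing but cannot exclude one. The labels state none. Median and mean differed in sign for the eosinophil, adhesion and eicosanoid lists, and median and fry for the adhesion (fry adjusted p = 0.0117), eicosanoid (0.0135) and mast cell lists (0.234). Other settings for the 4 comparisons with blockade were not run, and a fit to only the 2 groups is the main fit itself. At this depth changes near the floor of 3 counts, or below 2-fold, can be missed.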

Other observations

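The count of genes at equal depth and the scaling to library totals alone were chosen after seeing the data. Immediate early and heat shock genes, which respond within minutes to handling of tissue, were higher in resting lung in 14 of 28 cases and lower in 6, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0889, median log2 fold change -0.41). It passed without day 7 replicate 1 (adjusted p = 0.0391). Jun and Atf3 went from 633 ± 138 to 156 ± 34.7 CPM and from 821 ± 173 to 200 ± 44.3 CPM in the graft, while Nr4a2 and Dusp2 rose by 1.28 and 1.21 on the log2 scale. Genes of tissue remodelling and growth factors were higher in 14 of 30 cases and lower in 9, and 14 and 10 when adjusted over the list alone, without a call for the list (camera adjusted p = 0.287). Mmp12, the macrophage elastase, rose from 6.43 ± 1.06 to 76.8 ± 29.4 CPM and Spp1, the matrix protein osteopontin, from 82.6 ± 12.7 to 501 ± 134 CPM, while Ccn2, a growth factor of connective tissue, fell from 83.2 ± 23.5 to 4.40 ± 2.07 CPM. Endothelial markers (10 of 10, median -5.10) and epithelial markers (12 of 13, median -3.24) fell in the same libraries as Ccn2. Antimicrobial and phagocyte oxidase genes were higher in 13 of 20 cases and lower in 1, over all genes and adjusted over the list alone. Their median was 0.96 (camera adjusted p = 0.00213, adjusted p = 0.262 with an estimated correlation). Acod1, the enzyme that makes itaconate, rose from 972 ± 149 to 3883 ± 1119 CPM, and Camp, the cathelicidin precursor, was the member that fell. Monocyte and interstitial macrophage markers rose in the same libraries (12 of 14 higher, median 2.04).

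Genes of eicosanoid synthesis gave no call as a list (camera adjusted p = 0.926), with 4 of 16 higher and 3 lower over all genes and adjusted over the list alone. The median was 0.01, the mean -0.26 and the median with library totals alone -0.18. Pla2g4a, which releases arachidonic acid, rose by 1.41 ± 0.17 on the log2 scale, whereas Hpgd, which inactivates prostaglandins, fell from 424 ± 44.4 to 15.9 ± 5.34 CPM, and Alox15, the lipoxygenase of eosinophils, had 703 and 799 CPM without passing. The fall of Hpgd came beside lower endothelial markers (10 of 10, median -5.10) and epithelial markers (12 of 13, median -3.24), and its source cell was not tested. Adhesion molecules gave no call either (camera adjusted p = 0.926), with 6 of 21 higher and 5 lower, and 7 and 6 when adjusted over the list alone. Itgav rose by 1.09 ± 0.13 on the log2 scale, and Icam2 and Pecam1, both abundant in endothelium, had log2 fold changes of -2.29 ± 0.14 and -2.63 ± 0.18. With library totals alone 5 were higher and 9 lower, and the median of 0.17 became -0.01. The mean was -0.10. Chaperones and enzymes of the endoplasmic reticulum stress response were higher in 14 of 22 cases and lower in 1, and 16 and 2 when adjusted over the list alone. Their median was 0.55 (camera adjusted p = 0.00074, adjusted p = 0.421 with an estimated correlation). Survival and apoptosis genes were higher in 10 of 26 cases and lower in 3, over all genes and adjusted over the list alone. Their median was 0.33 (camera adjusted p = 0.027, adjusted p = 0.283 with an estimated correlation). With library totals alone 6 were lower. The higher ones held both the protective Bcl2a1 copies, with Bcl2a1d at 2.09 ± 0.15, and the pore-forming Bak1, at 2.19 ± 0.20 on the log2 scale. Ribosomal protein genes were higher in 22 of 35 cases, over all genes and adjusted over the list alone, by a median of 0.32 (camera adjusted p = 0.000119, adjusted p = 0.486 with an estimated correlation). Of these 6 were higher with library totals alone. The rises of these 3 lists came beside higher markers of monocytes and interstitial macrophages (12 of 14, median 2.04) and of T cells (12 of 12, median 2.30). Nuclear-retained RNAs (camera adjusted p = 0.736, 1 of 6 higher and 1 lower, and 1 and 3 when adjusted over the list alone) and sex-linked genes (camera adjusted p = 0.578, 0 of 4 higher or lower, also when adjusted over the list alone) gave no call. The median of the sex-linked genes was 0.12, and -0.06 with library totals alone.

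The resting libraries held more detected genes in spite of their lower depth. With every library thinned to 6666577 counts, 28349 ± 1546 genes had at least 1 count in resting lung and 23070 ± 1020 in the graft (exact two-sided permutation p = 0.00794). Olfactory and vomeronasal receptor genes summed to 346 ± 111 CPM in resting lung and 136 ± 53.2 CPM in the graft (exact two-sided permutation p = 0.00794). What caused these differences was not tested, and a technical difference between batches cannot be told apart from one between the groups.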
